A study of Mus musculus with 32 samples.

How the data were processed

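RNA from 12 arrays of cultured lymphoma cells and 20 arrays of mouse brain was measured on Affymetrix whole-transcript mouse gene arrays. The extraction entry of the labels reads as frozen sections and Trizol for every sample, the cultured lines included. The deposited values are intensities made with RMA in Affymetrix Expression Console, per the submitters' processing notes, and no version of either is given there. RMA corrects background, applies quantile normalization and summarises probes into probe sets. The deposited intensities run from 2.72 to 17825, so they stand on a linear scale and not on the log2 scale that the analysis plan had assumed, and log2 was taken before any other step, as the plan foresaw for that case. The sources used here do not say whether lines and brains were normalized together or at which probe-set level the values were summarised. The median intensity per array lay between 81.7 and 93.0. No depth in reads applies to arrays, and the number of arrays per group limits the precision. RMA gives no detection call, so a low intensity is not a measured absence. Where the mean of a group lies below the median of its arrays, residual background can shrink a difference, so the order of the largest differences is that of the measured values only.

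Of 35556 probe sets, 21789 carried 1 gene symbol in the probe table, 1621 carried several and 12146 carried none. Of those with 1 symbol, 21698 had an identifier found in the mouse gene table of assembly GRCm38.p6, which was used for names only, so no coordinates are given. They represent 19938 distinct genes. Each gene was represented by its probe set with the highest mean over the arrays of a fit. A probe set stayed in a fit where it exceeded its array's median over all non-control probe sets on at least as many arrays as the smallest group held. This left 9991 genes for the lines and 10572 genes for the brains. Counts of list genes are over the genes that passed. A gene below the median in every PBS brain could pass only through implanted brains. The share of tested list genes that rose against PBS is therefore partly set by the filter.

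Each of 6 comparisons was tested with limma 3.58.1 in R 4.3.3 on log2 intensities, with a group-means model, empirical Bayes moderation and Benjamini-Hochberg adjustment, two-sided. A gene was called at an adjusted p under 0.05. The line comparison used the 12 line arrays, and the brain comparisons used the 20 brain arrays in a single fit with a shared estimate of the spread. Differences are log2 fold changes with limma's standard error (SE), and list means are given with the standard deviation (SD). A total of 39 gene lists of cell types and pathways were fixed before the data were examined. Lists with at least 3 tested genes were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison.

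The mean log2 intensity of a list per brain, over its genes on the array without the filter, was compared between groups with a two-sided exact permutation test for 6 lists in 5 brain comparisons. Correlations of list means across the 15 implanted brains used values centred on their group and 100000 shuffles within groups. Overlaps between comparisons that share control arrays were set beside the overlap of independent lists, beside 20 simulations without any effect, and beside the median over 20 divisions of the control arrays between the comparisons. The genes called between the cultured lines were followed into the brains by the sign of their difference and by a difference of differences, in a limma fit over all 32 arrays.

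Genes are named by a rule fixed before the data were examined. It takes, per comparison, the 8 rising and 8 falling called genes with the largest change whose values did not overlap between the groups, the 3 genes with the smallest adjusted p of each list described, and 13 fixed genes where measured. The rule names genes in the text under any of its parts, and genes chosen after their values were seen are marked as such. Markers of brain regions were listed after the results were seen. The alternatives were quantile normalization, median centring, no filter or a stricter filter at percentile 75, the mean of a gene's probe sets, trended and robust moderation, array weights, the replicate number as a block, other sets of arrays in the fit, list means as covariates, the macrophage list without genes of the cultured lines, a minimum change, and leaving out each array in turn.

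The tests were tried on simulated data with the real arrays' means and spread, in which 200 genes were changed. For BAL17VII against BAL17 cells, 88% of 100 genes changed by 0.5 on the log2 scale and 100% of those changed by 1 were recovered among 9991 genes, and 7.39% of the calls were false. For BAL17 brains at day 21 against PBS brains, 79% and 98% were recovered among 10572 genes, with 6.84% false calls. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Probe sets with several gene symbols were left out, since their signal cannot be assigned to a gene, and probe sets without a gene name were counted separately.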

Results

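The data describe BAL17, a mouse B cell lymphoma line of BALB/c origin, and BAL17VII, a line derived from it. The study used them as a model of primary lymphoma of the central nervous system. RNA was profiled from 6 arrays of cultured BAL17VII cells and 6 of cultured BAL17 cells. Brains were profiled after implantation of 500000 cells, with 5 brains at day 21 for each line and 5 at day 28 for BAL17. A further 5 brains that received PBS were taken at day 28, and there was no PBS group at day 21. Correlations between arrays of a group ranged from 0.9796 to 0.9947. The labels do not say whether the arrays of a line came from separate cultures. Differences below are log2 fold changes ± SE of log2 intensity. For brains the SE rests on a spread shared by all groups, so it is too small where BAL17VII brains varied more than the others.

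The comparison of the cultured lines asks how BAL17VII cells differ from the line they derive from. BAL17VII cells had far higher levels of the genes that present antigen on MHC class II. H2-Aa rose by 4.43 ± 0.14, from a mean of 5.73 to 10.15, and Cd74, the invariant chain, rose by 4.06 ± 0.11 (n = 6 and 6 arrays). H2-Ea (5.45 ± 0.07), Dock10, a guanine nucleotide exchange factor (5.03 ± 0.08), Xlr (3.97 ± 0.21), Adgrg7 (3.57 ± 0.09), Dpp4 (3.52 ± 0.10) and Trim30a (3.44 ± 0.07) rose as well. The BAL17 means of these genes, from 4.27 for Xlr to 6.44 for Trim30a, lay below the medians of the named probe sets on the BAL17 arrays (6.54 to 6.64). Residual background can shrink such differences, so they are better read as lower bounds, and their order is left open. The largest measured falls were those of Rgs13, a regulator of G protein signalling in germinal centre B cells (-2.37 ± 0.07), the dopamine transporter gene Slc6a3 (-2.22 ± 0.06) and the interleukin 7 receptor gene Il7r (-2.11 ± 0.06). Ryr2 (-1.97 ± 0.06), Tnnt3 (-1.92 ± 0.10), Hmgcs1 (-1.78 ± 0.06), Cd3g (-1.62 ± 0.11) and Kynu (-1.61 ± 0.08) also fell. Of 9991 genes tested, 3418 were called, 1840 higher and 1578 lower in BAL17VII, and 150 of the rises and 50 of the falls were at least a doubling or halving. The values of 1937 genes did not overlap between the lines, 19.4% where chance gives 0.216%. H2 genes, Trim30a and Xlr belong to families of similar copies, and shared probes leave their values uncertain.

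All 11 tested genes of the MHC class II list rose, and 11 did so adjusted over the list alone, with H2-Eb1 at 2.15 ± 0.09 (list adjusted p = 5.23e-13, and 0.00887 with an estimated correlation). Of 13 genes that respond to type I interferon, 12 rose, and 12 did so adjusted over the list alone, led by Rtp4 (3.32 ± 0.12), Ddx60 (2.07 ± 0.09) and the RNA sensor gene Ddx58 (1.64 ± 0.08). That list had an adjusted p of 4.68e-14, and 0.0175 with an estimated correlation. Of 9 interferon gamma response genes 7 rose, and 8 did so adjusted over the list alone, among them Ciita, the transactivator of MHC class II genes (1.58 ± 0.11), and Irgm1 (1.14 ± 0.09). Its adjusted p of 0.000141 became an adjusted p = 0.118 with an estimated correlation. Of 20 B cell receptor signalling genes 16 rose and 1 fell, and 17 rose and 1 fell adjusted over the list alone, with Prkcb at 1.24 ± 0.08, Inpp5d at 0.74 ± 0.06 and Btk at 0.57 ± 0.05. Of 13 NF-kB targets 11 rose and 1 fell, and 12 rose and 1 fell adjusted over the list alone, with Birc3 at 1.01 ± 0.07 and Cd40 at 0.85 ± 0.08. These lists had adjusted p = 8.04e-08 and 7.69e-06, and adjusted p = 0.13 and 0.0823 with an estimated correlation. The monocyte and macrophage list had 21 genes on the array, of which 6 passed the intensity filter. Of these 6 genes 5 rose, and 5 did so adjusted over the list alone (list adjusted p = 2.73e-06, and 0.0113 with an estimated correlation).

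DNA replication and cholesterol synthesis genes were lower in BAL17VII cells. Of 23 replication genes 22 fell, and 22 did so adjusted over the list alone, with Mcm4 at -1.26 ± 0.07 and Rrm2 at -1.14 ± 0.06 (list adjusted p = 3.26e-17, and 0.0227 with an estimated correlation). Of 15 cholesterol synthesis genes 14 fell, and 14 did so adjusted over the list alone, with Idi1 at -1.53 ± 0.07 and Sqle at -1.17 ± 0.06 (list adjusted p = 1.87e-14, and 0.0113 with an estimated correlation). Mitosis genes were not called as a list (adjusted p = 0.229), with 8 of 20 lower and 3 higher, 8 and 4 adjusted over the list alone. Mki67 had a difference of -0.12 ± 0.08 (adjusted p = 0.24). The B lineage list was not called either (adjusted p = 0.229), with 8 of 17 genes higher and 3 lower, the same counts adjusted over the list alone, and Cd79a had a difference of -0.05 ± 0.09. The germinal centre list had a median of 0.08 and a mean of -0.04, camera gave no call (adjusted p = 0.979), and fry called it lower.

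Implanted BAL17 cells against PBS asks which transcripts were higher and which were lower in brains with a growing lymphoma. At day 21 the brains gained genes of dividing B cells. Top2a, a topoisomerase of dividing cells, rose by 4.37 ± 0.52, from 5.33 to 9.70, and Rgs13 rose by 4.32 ± 0.36 (n = 5 and 5 brains). Among called genes without overlap, P2ry10 (3.91 ± 0.44), the proto-oncogene Myc (3.84 ± 0.33), Stap1 (3.76 ± 0.40), H2-Ea (3.75 ± 0.47), Bub1 (3.74 ± 0.46) and Knl1 (3.73 ± 0.41) rose too. Apart from Myc at 6.90, their PBS means, from 3.61 for P2ry10 to 5.85 for H2-Ea, lay below the medians of the named probe sets on the PBS arrays (6.69 to 6.74), as that of Top2a did, so these rises are better read as lower bounds without an order. Prl, the prolactin gene of the pituitary, fell most (-2.77 ± 1.06), but it ranged from 5.79 to 10.46 in the PBS brains. Fabp7 (-2.09 ± 0.33), the myelin lipid enzyme gene Ugt8a (-1.36 ± 0.17), Cryab (-1.36 ± 0.18), Nrep (-1.35 ± 0.21), Lcat (-1.35 ± 0.16), the astrocyte gene S100b (-1.32 ± 0.23) and H2bc4 (-1.31 ± 0.20) also fell. Of 10572 genes, 5124 were called, 1382 higher and 3742 lower, and the median over all genes was -0.13. Rises of at least a doubling numbered 236 against 42 falls of that size. The values of 3034 genes did not overlap, 28.7% where chance gives 0.794%. Since PBS brains were taken at day 28, the day differs along with the cells.

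Of 17 B lineage genes 16 rose and 1 fell at day 21, the same counts adjusted over the list alone, among them Cd79b, a chain of the B cell receptor (2.84 ± 0.30), Pou2af1 (2.31 ± 0.22), Cd37 (1.90 ± 0.21), Ms4a1 (2.31 ± 0.40) and Cd79a (1.75 ± 0.35). All 18 mitosis genes and all 18 DNA replication genes rose, the same counts adjusted over the list alone, with Bub1b at 3.01 ± 0.30, Mcm6 at 2.96 ± 0.27 and Mki67 at 3.37 ± 0.36. Of 20 MYC target genes 19 rose, as they did adjusted over the list alone, with Nop58 at 1.47 ± 0.12. Adjusted p values for these lists were 2.89e-13, 6.51e-20, 8.76e-19 and 8.28e-19. With an estimated correlation they were 0.0748 and 0.0748 for B lineage and mitosis, and 0.0294 and 0.0294 for replication and MYC targets. The apoptosis list rose as well, with 8 of 14 genes higher and 2 lower, the same adjusted over the list alone, led by Bcl2 (1.99 ± 0.16), Casp8 (1.41 ± 0.14) and Bcl2l11 (1.29 ± 0.13). Its adjusted p was 7.01e-05, and 0.0294 with an estimated correlation.

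Immune genes rose along with them. Of 21 macrophage genes on the array 7 passed the filter. All 7 rose, as they did adjusted over the list alone, with the lysozyme gene Lyz2 at 1.57 ± 0.30 and Cybb at 1.99 ± 0.38 (list adjusted p = 8.18e-05, and adjusted p = 0.0748 with an estimated correlation). Genes dim in PBS brains could pass only by being high in implanted brains, so that share was partly fixed beforehand. Of 8 MHC class II genes 6 rose, as they did adjusted over the list alone, with H2-Aa at 2.86 ± 0.46 and Cd74 at 2.36 ± 0.41 (list adjusted p = 0.000115, and adjusted p = 0.144 with an estimated correlation). Of 10 MHC class I genes 8 rose, as they did adjusted over the list alone, with B2m at 1.35 ± 0.19 and Erap1 at 1.36 ± 0.16 (list adjusted p = 3.22e-06, and adjusted p = 0.0748 with an estimated correlation). Of 11 interferon gamma response genes 7 rose, as they did adjusted over the list alone, with Cd274, which encodes PD-L1, at 1.79 ± 0.22 (list adjusted p = 0.00019, and adjusted p = 0.24 with an estimated correlation). Brain cell genes fell at the same time. Lymphoma RNA takes a share of the RNA measured, so dilution alone can lower brain genes, and it was not tested apart from other causes. Of 15 myelin genes 13 fell, as they did adjusted over the list alone, with Mag at -0.98 ± 0.17, Ermn at -1.10 ± 0.20 and Mbp at -0.39 ± 0.10. Of 21 neuron genes 17 fell, 18 adjusted over the list alone, with Syn1 at -0.77 ± 0.12 and Tubb3 at -0.79 ± 0.12, while Snap25 had -0.08 ± 0.05. Region markers listed after the results were seen differed beside it, with a cortical mean of 8.13 against 8.70 in PBS brains and a cerebellar mean of 8.59 against 9.45. Of 11 astrocyte genes 9 fell and 1 rose, as they did adjusted over the list alone, with Aqp4 at -0.97 ± 0.15. The 3 lists had adjusted p = 0.00156 (myelin), 0.000115 (neuron) and 0.00932 (astrocyte), and adjusted p = 0.37, 0.112 and 0.363 with an estimated correlation. Of 14 microglia genes 9 fell and 2 rose, as they did adjusted over the list alone, with P2ry13 at -0.81 ± 0.12, and the list was not called (adjusted p = 0.265).

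BAL17VII brains at day 21 had higher B cell and division genes than PBS brains, but not in every brain. Replicate 1 stood at PBS levels in list means and Top2a, with a B lineage mean of 6.03, a mitosis mean of 5.71 and Top2a at 5.24. By the rule of no overlap it still lay above every PBS brain in the rising genes named next. Among called genes whose values did not overlap, H2-Ea (3.22 ± 0.47), Stap1 (2.67 ± 0.40), Cd2 (2.27 ± 0.36), Ncapg (2.11 ± 0.32), Cmah (1.97 ± 0.25), Btk (1.91 ± 0.24), Rrm2 (1.60 ± 0.19) and Cks1b (1.57 ± 0.23) had the largest measured rises against PBS (n = 5 and 5 brains), and apart from Cks1b their PBS means lay below the array medians, so their order is left open. Among called genes without overlap the falls were led by Pamr1 at -0.66 ± 0.14, with Kcnk10 at -0.57 ± 0.11, Cpne9 at -0.55 ± 0.12, the neuronal calcium sensor gene Hpca at -0.50 ± 0.13 and Zic5 at -0.49 ± 0.12. Pituitary transcripts moved with the group, as genes read after their values were seen. Gh rose from 6.03 to 10.02 (SE 0.82), Prl had a difference of 3.33 ± 1.06 (adjusted p = 0.0675), and the mean of 8 pituitary markers was 7.82 ± 1.32 (SD) against 6.20 ± 0.31. Of 10572 genes, 577 were called, 379 higher and 198 lower, and 91 of the rises and 1 of the falls were at least a doubling or halving. Of 17 B lineage genes 12 rose, 15 adjusted over the list alone. Of 18 mitosis genes 16 rose, 17 adjusted over the list alone, with Mki67 at 2.22 ± 0.36 and Birc5 at 1.34 ± 0.20. The SD of the mitosis mean was 0.728 in BAL17VII brains, 0.064 in PBS brains and 0.05 in BAL17 brains at day 28. The shared SE thus understates the spread of such genes in BAL17VII brains. Of 18 replication genes 12 rose, 13 adjusted over the list alone. Adjusted p for these lists was 7.07e-16, 2.98e-25 and 8.01e-17, and adjusted p = 0.0512, 0.0505 and 0.0505 with an estimated correlation. Of 8 MHC class II genes 4 rose, 6 adjusted over the list alone, with H2-Aa at 2.15 ± 0.46 and Cd74 at 1.99 ± 0.41 (list adjusted p = 5.58e-06, and adjusted p = 0.0804 with an estimated correlation). Of 18 reactive astrocyte genes on the array 7 were tested. Of these 7 genes 3 rose, as they did adjusted over the list alone, with Hspb1 at 0.80 ± 0.16 and Osmr at 0.52 ± 0.14 (list adjusted p = 0.000102, and adjusted p = 0.0515 with an estimated correlation). Cultured BAL17VII cells themselves had Vim at 10.62 and Cd44 at 8.99, both on this list, so implanted cells can raise some of its genes. No myelin gene of 15 was called, adjusted over the list alone included (list adjusted p = 0.501). The count of 577 rested on single brains. Without BAL17VII replicate 2 or 3 it was 244 or 260, without PBS replicate 4 or 5 it was 357 in each case, and a fit on these groups' arrays gave 255, with 225 higher and 30 lower. Without BAL17VII replicate 4 it was 1285, with 544 higher and 741 lower, and 574 of the 577 calls were among them.

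**Figure D1:**
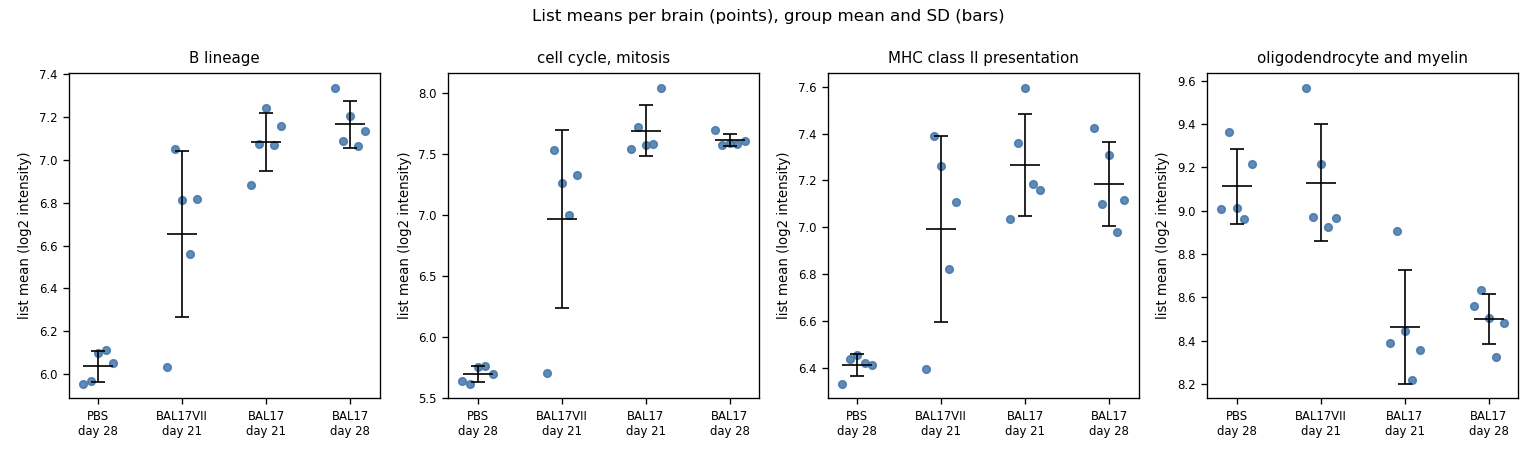
Mean log2 intensity per brain of the B lineage, mitosis, MHC class II and myelin lists (points, 5 brains per group), with the group mean and SD (bars), for PBS, BAL17VII and BAL17 brains. The B lineage mean of BAL17 brains lay between 6.88 and 7.34, above the PBS brains at 5.96 to 6.11, and BAL17VII brains ranged from 6.03 to 7.05.

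At day 28 BAL17 brains again had higher B cell and division genes than PBS brains, here of the same day, and lower myelin, choroid plexus, neuron and astrocyte genes. Dilution by lymphoma RNA can lower brain genes here too, which was not tested. Among called genes without overlap, Top2a (4.28 ± 0.52), H2-Ea (4.05 ± 0.47), Rgs13 (3.89 ± 0.36), Stap1 (3.72 ± 0.40), Bub1 (3.61 ± 0.46), Knl1 (3.53 ± 0.41), P2ry10 (3.38 ± 0.44) and Myc (3.25 ± 0.33) had the largest measured rises (n = 5 and 5 brains), against the same low PBS means apart from Myc. Prl (-3.13 ± 1.06), Nexn (-1.22 ± 0.16), the myelin gene Mag (-1.10 ± 0.17), Sv2c (-1.08 ± 0.20), Ntng1 (-1.08 ± 0.15), Rarb (-1.03 ± 0.21), Car2 (-0.99 ± 0.20) and Rnd2 (-0.99 ± 0.29) fell most under the same condition. Of 10572 genes, 3509 were called, 962 higher and 2547 lower, and the median over all genes was -0.11. Rises of at least a doubling numbered 191 against 15 falls of that size. Of 17 B lineage genes 16 rose, as they did adjusted over the list alone, with Cd79b at 2.98 ± 0.30 and Ms4a1 at 3.02 ± 0.40, and all 18 mitosis genes rose, as they did adjusted over the list alone (list adjusted p = 2.39e-20 and 7.69e-27, and 0.0272 and 0.0273 with an estimated correlation). Of 7 macrophage genes 6 rose, 7 adjusted over the list alone, with Lyz2 at 1.85 ± 0.30 (list adjusted p = 9.19e-07, and 0.0324 with an estimated correlation). Of 15 myelin genes 14 fell, as they did adjusted over the list alone, with Trf at -0.90 ± 0.16 (list adjusted p = 4.66e-05, and adjusted p = 0.271 with an estimated correlation). Of 8 choroid plexus and ependyma genes 7 fell, as they did adjusted over the list alone, with Sostdc1 at -1.02 ± 0.21 and Otx2 at -0.94 ± 0.18 (list adjusted p = 0.00219, and adjusted p = 0.271 with an estimated correlation). Of 21 neuron genes 14 fell, as they did adjusted over the list alone, with Tubb3 at -0.61 ± 0.12 (list adjusted p = 0.00907, and adjusted p = 0.271 with an estimated correlation). Of 11 astrocyte genes 6 fell, 7 adjusted over the list alone, with Aqp4 at -0.74 ± 0.15 (list adjusted p = 0.0234, and adjusted p = 0.379 with an estimated correlation). Region markers listed after the results were seen differed beside these falls, with a striatal mean of 7.68 against 8.79 in PBS brains, a thalamic mean of 8.25 against 8.86 and a cerebellar mean of 9.16 against 9.45.

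The comparison of the lines after implantation asks whether they leave different profiles in the brain at the same day. Several genes of lymphocytes were lower in BAL17VII than in BAL17 brains. Among called genes without overlap, those lower by the largest measured amounts were Rgs13 (-3.18 ± 0.36), Casp4 (-2.38 ± 0.24), Slamf7 (-2.35 ± 0.26), the phosphatase gene Ptpn22 (-2.26 ± 0.26), P2ry10 (-2.09 ± 0.44), Map3k15 (-2.01 ± 0.19), Ctse (-1.88 ± 0.29) and Il7r (-1.84 ± 0.17; n = 5 and 5 brains). Fabp7 (2.36 ± 0.33), H2bc4 (1.45 ± 0.20), Hmcn1 (1.44 ± 0.17), Abi3bp (1.44 ± 0.13), Ugt8a (1.43 ± 0.17), Cryab (1.38 ± 0.18), Tnfaip6 (1.32 ± 0.22) and Lxn (1.32 ± 0.15) were higher. Larger differences with overlapping values were those of Prl (6.10 ± 1.06) and Gh (4.44 ± 0.82), read after their values were seen, and the mean of 8 pituitary markers was 7.82 ± 1.32 (SD) in BAL17VII and 5.78 ± 0.11 in BAL17 brains, so this tissue differs beside every gene group below. Of 10572 genes, 2852 were called, 2094 higher and 758 lower in BAL17VII brains, but at a doubling or halving the balance was the opposite, with 22 higher and 44 lower. Of 17 B lineage genes 11 were lower, and 12 were lower and 1 higher adjusted over the list alone, with Pou2af1 at -1.06 ± 0.22 (list adjusted p = 5.35e-06, and adjusted p = 0.307 with an estimated correlation). Of 18 replication genes 16 were lower, as they were adjusted over the list alone, with Mcm4 at -0.85 ± 0.10 (list adjusted p = 1.19e-12, and adjusted p = 0.0844 with an estimated correlation). Of 20 MYC target genes 13 were lower, 16 adjusted over the list alone, with Myc at -1.72 ± 0.33 (list adjusted p = 1.63e-13, and adjusted p = 0.0844 with an estimated correlation). Of 15 myelin genes 12 were higher, as they were adjusted over the list alone, with Ermn at 1.15 ± 0.20, and of 21 neuron genes 9 were higher, as they were adjusted over the list alone, with Tubb3 at 0.72 ± 0.12. Of 14 microglia genes 8 were higher, 9 adjusted over the list alone, with Cx3cr1 at 0.61 ± 0.10 and P2ry13 at 0.66 ± 0.12. These lists had adjusted p = 5.35e-06, 0.000589 and 0.00476, and adjusted p = 0.312, 0.253 and 0.428 with an estimated correlation.

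With the B lineage mean of each brain as a covariate 348 genes were called, and with the striatum and cortex marker means as covariates, a setting chosen after the data were seen, 599 were called, 288 higher and 311 lower. BAL17VII replicate 1 had a B lineage mean of 6.03, inside the PBS range, and without it 1761 genes were called. A fit on the arrays of these groups alone gave 1671, with 1223 higher and 448 lower.

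The comparison of days asks how the BAL17 brains changed from day 21 to day 28. No list fixed beforehand covers brain regions, so single genes are given. Among called genes without overlap, the neuronal transcription factor genes Neurod6 (1.10 ± 0.21), Tbr1 (0.72 ± 0.15) and Satb1 (0.69 ± 0.14) rose, with Mlip (0.98 ± 0.14), Kcnh7 (0.79 ± 0.14), Vxn (0.76 ± 0.17), Fmn1 (0.66 ± 0.12) and Rab11b (0.65 ± 0.12; n = 5 and 5 brains). Tac1 (-1.46 ± 0.33), Rgs9 (-1.29 ± 0.25), Prkcd (-1.14 ± 0.22), the enkephalin gene Penk (-1.09 ± 0.19) and the dopamine receptor genes Drd2 (-1.06 ± 0.27) and Drd1 (-1.03 ± 0.25) fell. Ptpn22 (-1.23 ± 0.26) and Il7r (-1.01 ± 0.17), both expressed in lymphocytes, fell as well. Of 10572 genes, 186 were called, 127 higher and 59 lower, but at a doubling or halving 1 was higher and 10 were lower. Of 8 choroid plexus and ependyma genes 4 fell, 7 adjusted over the list alone, with Clic6 at -1.10 ± 0.23, Kcnj13 at -0.64 ± 0.14 and Folr1 at -0.61 ± 0.15 (list adjusted p = 8.23e-10, and adjusted p = 0.225 with an estimated correlation). Of 21 neuron genes 3 rose, and 7 rose and 1 fell adjusted over the list alone (list adjusted p = 0.000176, and adjusted p = 0.363 with an estimated correlation). No gene of the 17 tested from the B lineage list was called, adjusted over the list alone included (list adjusted p = 0.391). Over 10 striatal markers the mean was 8.63 ± 0.14 (SD) at day 21, 7.68 ± 0.34 at day 28, 8.79 ± 0.54 in PBS brains and 8.70 ± 0.36 in BAL17VII brains. Over 9 cortical markers it was 8.13 ± 0.13 at day 21 and 8.65 ± 0.14 at day 28, 8.70 ± 0.11 in PBS brains and 8.45 ± 0.24 in BAL17VII brains, so day 28 lay near the PBS mean and day 21 below it. The count of 186 was 45, 62 or 109 without day 28 replicate 1, 3 or 5, and 65, 294, 99 or 78 without day 21 replicate 1, 2, 4 or 5. It was 311 after quantile normalization, 609 with array weights, 322 from these groups' arrays, and 0 with the striatum and cortex marker means as covariates, which were picked partly from these genes.

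**Figure D2:**
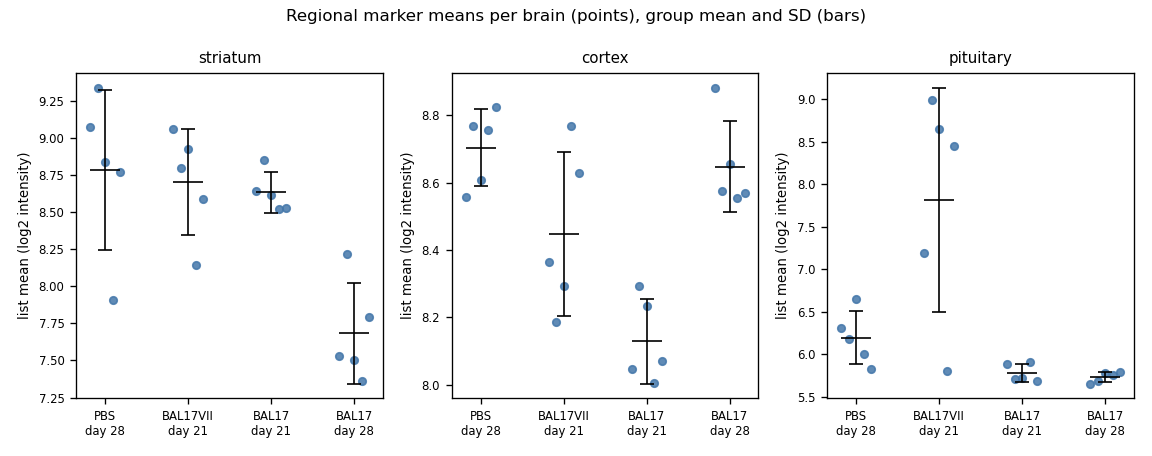
Mean log2 intensity per brain of striatal, cortical and pituitary marker genes (points, 5 brains per group), with the group mean and SD (bars). The striatal mean of BAL17 brains was 8.63 at day 21 and 7.68 at day 28, and the PBS brains ranged from 7.91 to 9.34.

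List means per brain set the amount of each cell type's transcripts side by side. The B lineage mean was 7.09 ± 0.14 (SD, n = 5) in BAL17 brains at day 21, 7.17 ± 0.11 at day 28, 6.66 ± 0.39 in BAL17VII brains and 6.04 ± 0.07 in PBS brains. BAL17 brains exceeded PBS by 1.05 at day 21 and 1.13 at day 28, higher in 5 of 5 brains each time (exact permutation p = 0.00794, the smallest this design allows, adjusted p = 0.0397 over 30 tests). BAL17VII brains exceeded PBS by 0.62, with 4 of 5 brains above every PBS brain (exact permutation p = 0.0317, adjusted p = 0.0866), and by 0.774 without BAL17VII replicate 1 (exact permutation p = 0.00794, not adjusted). Against BAL17 brains at day 21 they differed by -0.43 (exact permutation p = 0.0159, adjusted p = 0.0529), and by -0.275 without BAL17VII replicate 1 (exact permutation p = 0.0397, not adjusted). The T cell mean was higher than in PBS brains by 0.30 in BAL17 brains at day 21 and by 0.27 at day 28, and the macrophage mean by 0.69 and 0.71, in 5 of 5 brains each (exact permutation, adjusted p = 0.0397). In BAL17VII brains neither passed, with 0.20 for the T cell mean (exact permutation, adjusted p = 0.119) and 0.52 for the macrophage mean (exact permutation, adjusted p = 0.0529). Cultured BAL17 cells themselves had the macrophage list genes Cybb at 7.65 and Plac8 at 7.44, so implanted cells can raise part of that mean. Without the list's genes above the filter in the cultured lines, a setting chosen after the data were seen, 15 genes gave 0.48 and 0.51 in BAL17 brains (exact permutation, adjusted p = 0.0397). They gave 0.28 in BAL17VII brains (exact permutation, adjusted p = 0.0529). Most T cell genes lay under the intensity filter. Without it, 5 of 19 rose in BAL17 brains at day 21, namely Cd2, Cd3e, Cd3g, Ctla4 and Zap70, and at day 28 Cd2 and Cd3g rose and 1 gene fell. Cultured BAL17 cells themselves had Cd2 at 9.48 and Cd3g at 7.35, so these genes do not mark T cells here.

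Across the 15 implanted brains the macrophage mean followed the B lineage mean after centring on the groups, with Pearson r = 0.921 (permutation p = 0.00012, adjusted p = 0.00084 over 7 relations) and Spearman rho = 0.904 (permutation p = 3e-04, adjusted p = 0.0021). Without the 2 brains farthest from the median, BAL17VII replicates 1 and 4, r was 0.763 (permutation p = 0.00362). Without the genes above the filter in the cultured lines r was 0.806 (permutation p = 0.00067, adjusted p = 0.00469) and rho 0.836 (permutation p = 0.00139, adjusted p = 0.00973), and r was 0.671 without those brains (permutation p = 0.0144). The T cell mean had r = 0.741 (permutation p = 0.0189, adjusted p = 0.0649) and rho = 0.604 (permutation p = 0.0519), and without those brains r was 0.43. The cytotoxic and NK cell mean had r = 0.724 (permutation p = 0.0278, adjusted p = 0.0649) and rho = 0.7 (permutation p = 0.0158), and r = 0.609 without them. None of the relations with microglia (r = 0.181, rho = 0.375), reactive astrocytes (r = 0.444, rho = 0.361), neurons (r = -0.506, rho = -0.204) or myelin (r = -0.458, rho = -0.014) passed the threshold, with permutation p = 0.569, 0.131, 0.287 and 0.186 for r and 0.203, 0.206, 0.555 and 0.968 for rho.

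The brain comparisons shared called genes, and they also share control arrays. Between BAL17 at day 21 and at day 28, both against PBS, 904 genes rose and 2163 fell in both, where independent lists would give 125.8 and 901.5. Across genes, which are not independent replicates, the changes correlated at r = 0.922, and their covariance was 0.1504 against 0.0074 simulated from the shared PBS arrays alone. With the PBS arrays split between the comparisons, 626 rose and 956.5 fell in both (median over 20 splits) and r was 0.87. Between BAL17 and BAL17VII at day 21, 359 rose and 191 fell in both, where independent lists would give 49.5 and 70.1, with r = 0.773 and a covariance of 0.0858 against 0.0075 simulated. Split PBS arrays gave 177.5 and 24. Between BAL17VII at day 21 and BAL17 at day 28, 357 rose and 161 fell in both, where independent lists would give 34.5 and 47.7, with a covariance of 0.0711 against 0.0073 simulated. Split PBS arrays gave 175 and 13.5. For BAL17VII at day 21 and BAL17 at day 28, both against BAL17 at day 21, 104 genes were higher and 30 lower in both, where independent lists would give 25.2 and 4.2, with r = 0.524 and a covariance of 0.0261 against 0.0074 simulated. Split control arrays gave 3 and 6, with r = 0.358. Simulations without any effect gave an overlap of 0 each time. That was fixed beforehand, since adjusted calls are rare without an effect, so the 0 is no reference for the overlaps. The simulated genes were also drawn independently of each other. Simulated r was 0.505, 0.501, 0.496 and 0.501 in this order of pairs: BAL17 with BAL17VII at day 21, BAL17 at both days, BAL17VII with BAL17 at day 28, and the pair against BAL17 at day 21.

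The last question is whether the genes that set the lines apart in culture also differ in the brains at day 21. In the fit on all 32 arrays, 3317 genes were called between the cultured lines. Of these, 52.8% differed in the same direction between BAL17VII and BAL17 brains (exact permutation p = 0.175, 252 splits). The share was 54.3% for the 2525 genes above the median level in PBS brains (exact permutation p = 0.0476) and 48.1% for the other 792 (exact permutation p = 0.73). Without BAL17VII brain replicate 1, a setting chosen after the data were seen, the share over all was 53.7%. Rgs13 and Il7r were lower in BAL17VII in both materials, by -2.37 and -3.18 and by -2.11 and -1.84, and Dock10 was higher in both, by 5.03 and 0.77. H2-Aa was higher by 4.43 in the cultured cells and had a difference of -0.71 (adjusted p = 0.177) in the brains, and for Cd74 these values were 4.06 and -0.37 (adjusted p = 0.444). The difference of differences was 5.13 for H2-Aa (adjusted p = 6.21e-09) and 4.43 for Cd74 (adjusted p = 1.18e-08). Lymphoma RNA is only a share of the brain RNA, so a line difference shrinks there by dilution, and a difference of differences does not by itself show that the cells changed. Hmgcs1 was lower in cultured BAL17VII cells (-1.78) and higher in BAL17VII brains (0.89), a difference of -2.67 (adjusted p = 5.2e-13). Of 13 cholesterol synthesis genes 8 were higher in BAL17VII than in BAL17 brains (list adjusted p = 0.00757, and adjusted p = 0.498 with an estimated correlation). Of 15 myelin genes 12 were higher there too. The sign of Hmgcs1 in the brains need not come from the lymphoma cells, which was not tested. Across 8416 genes tested in both materials the changes correlated at r = 0.056. There, 233 genes were higher in both and 197 lower in both, where independent lists would give 199.8 and 121.8. A further 345 were called in opposite directions. No count for independent lists was computed for these, so the 345 do not show that line differences reverse in the brain.

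**Figure D3:**
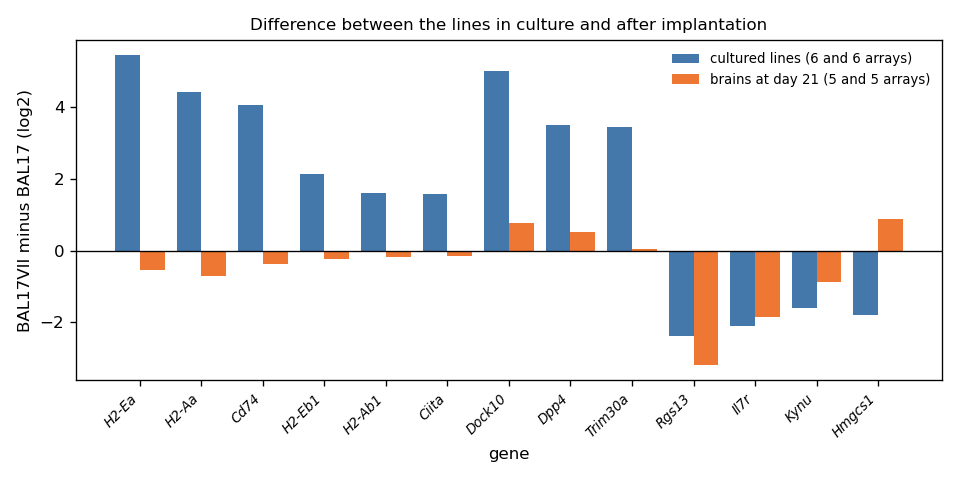
Difference between BAL17VII and BAL17 (log2) for 13 genes in cultured cells (blue, 6 and 6 arrays) and in brains at day 21 (orange, 5 and 5 arrays). H2-Aa stands at 4.43 in culture and -0.71 in the brains, and Rgs13 at -2.37 and -3.18.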

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

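Whether chance could form such groups was tested by dividing the same arrays in other ways, a test fixed before the data were examined, with 100 divisions per comparison and the real one included. Of 100 divisions, only 1, the real one, gave as many called genes as the 3418 between the cultured lines, and the highest other count was 2. The same held for 1 of 100 for BAL17 brains at day 28 against PBS (3509, highest other 153), and for day 28 against day 21 (186, highest other 5). It held for 1 of 100 for BAL17VII brains against PBS (577, highest other 279), and for BAL17 brains at day 21 against PBS (5124, highest other 2830, where BAL17 replicate 2 changed places with PBS replicate 3). For BAL17VII against BAL17 brains at day 21, 2 of 100 gave as many, the real one with 2852 and another with 3200. The share of divisions with as many calls lay under 0.05 in each comparison. For BAL17VII against BAL17 brains the real division was not the highest, so chance is not excluded there. The division with 3200 calls exchanged replicate 2 of both groups, and the next counts of 2588 and 1773 also moved BAL17 replicate 2 out of its group. The samples thus hold a structure besides the real groups, and the 2852 genes cannot be credited to the line alone. BAL17 replicate 2 at day 21 lay above its 4 group mates in 18 of 34 list means and below them in 0, among them the myelin list at 8.91 against 8.22 to 8.45 and the oxidative phosphorylation list at 10.39 against 9.72 to 10.03. This look at replicate 2 was chosen after the counts were seen. Without that brain 3790 genes were called between the implanted lines.

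All tests on a single brain were chosen only after the result was seen, and so were the genes read from it. BAL17VII replicate 1 at day 21 had a B lineage mean of 6.03, a mitosis mean of 5.71 and Mki67 at 5.59, levels of the PBS brains. A swap with a PBS brain was excluded, since the highest PBS B lineage mean minus the lowest of the other implanted brains was -0.445. Against a failed array stand a myelin mean 0.204 above the highest PBS brain (SD of PBS brains 0.171) and a hypothalamus mean of 7.89 against at most 6.62. Quantile normalization gives every array the same distribution, so a loss of signal in some genes can raise others. A failed array is therefore not excluded, and the lowest correlation of this array within its group was 0.9796. Tissue without implanted cells, whether by a wrong label, failed growth or the part of the brain taken, stays open. Replicate 1 lay above every PBS brain in the rising genes without overlap, such as H2-Ea, Stap1 and Rrm2. Those genes were picked for that, so they do not settle the question. The reactive astrocyte mean of replicate 1 lay 0.127 above the highest PBS brain, and its Pmch, a hypothalamic gene, was 11.02.

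For the shift between days, all tests were chosen only after the result was seen. On 5 striatal markers other than Tac1, Rgs9, Penk, Drd1 and Drd2, the difference of day 28 from day 21 was -0.715 (exact permutation p = 0.00794), and 3 of them are among the 186 genes called, so they do not form an independent test. With the B lineage mean as a covariate the difference was -0.684. That mean was 7.09 at day 21 and 7.17 at day 28, so the covariate could move the difference little whatever the cause. The similar means argue against the amount of lymphoma as the whole cause, and the covariate adds nothing to them. The part of the brain in the sample could not be told apart from the day. Single PBS brains spanned 1.269 in these markers, but that spread rests on PBS replicate 4, without which it was 0.471, less than the difference between the days.

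For MHC class II and interferon gamma genes the tests were again chosen only after the result was seen, and they compare brain with line arrays, a contrast outside the plan. Cd74 in BAL17 brains at day 21 lay 1.57 above the cultured line and 2.36 above PBS brains, and H2-Aa lay 3.01 and 2.86 above them, as H2-Eb1, Cxcl9 and Iigp1 also did, 5 of 23 list genes or 21.7%. At day 28 it was 4 of 23, or 17.4%. Over all 12315 genes it was 0.739% at day 21. On a common scale a mixture of unchanged cells and tissue cannot give such values. A general difference in scale between line and brain arrays is not seen. The 5187 genes outside the lists at the same levels in both sources had a median excess over the line of -0.102 (SD 0.337). The 5 genes had 1.57, but they were picked for their excess, so that contrast was partly fixed beforehand. Of the 5187 genes, 2.04% reached 0.766, the smallest excess of the 5. A difference in scale that touches single genes is not excluded. Host immune cells as carriers stay open, with r = 0.797 to the macrophage mean over 10 brains (permutation p = 0.00869, adjusted p = 0.0174 over 2 relations, rho = 0.83, permutation p = 0.0104). Without the 2 farthest brains r was 0.628 over 8 brains (permutation p = 0.137), so passing the test, though not the sign, rests on them, and the T cell mean had r = 0.49 (permutation p = 0.18) and rho = 0.43 (permutation p = 0.243). The rules that sort explanations into excluded and open were rewritten after values had been seen, and the tests of the failed array and of the scale replaced earlier ones that had decided nothing or had been circular.

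The measured line difference was unlike between culture and brain for 3261 genes by the difference of differences. Brain tissue dilutes any line difference, so this count does not show that the cells themselves differed between the materials. Among probe sets without a gene name, 834 changed in BAL17 brains at day 21 against PBS, 104 in BAL17VII brains and 454 in BAL17 brains at day 28, of 4405 above the intensity filter, and they were not analysed further here. None of 36 list means had a lone brain that stood apart by the rule fixed beforehand (0 cases). The rule did not flag BAL17VII replicate 1 at day 21 either, with a B lineage mean of 6.03 against 6.56 to 7.05 in its group. The count of 0 thus does not show that no brain stood apart.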

How the results depend on the processing

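Across alternatives, single results stayed called or stayed uncalled in 15266 cases, lost a call in 706 and gained a call in 233. In 13 cases the sign reversed where at least 1 setting gave a call. The sizes of single results were not compared in these labels. Counts stayed within 1.5 times in 155 cases and moved in 48. The cause was not tested for moved or reversed values, except where the setting forces the change. In the order lines, BAL17 day 21, BAL17VII and BAL17 day 28 against PBS, BAL17VII against BAL17, and day 28 against day 21, a change of at least 1 left 200, 278, 92, 206, 66 and 11 genes by construction. The replicate block gave 3479, 5374, 791, 3742, 3169 and 241. Only 1 to 3 pairs of equal number per pair of groups correlated above 0.1. Their mean r, from 0.02 to 0.198, still exceeded that of other pairs in every pair of groups. Whether the numbers pair the samples is thus not settled. Camera with an estimated correlation called 5, 4, 0, 9, 0 and 0 lists. Fry called 21 lists for the lines and 2 between the days, and reversed the germinal centre list in the lines (-0.035). The filter at percentile 75 gave 2854, 333, 2031 and 1889 genes for BAL17 day 21, BAL17VII and BAL17 day 28 against PBS and for BAL17VII against BAL17. Groups without overlap held 1937 genes in the lines, 3034 in BAL17 day 21 against PBS, 1155 between the implanted lines and 584 between the days. Array weights gave 873 for BAL17VII against PBS and 609 between the days, where quantile normalization gave 311. The arrays of the compared groups alone gave 255, 1671 and 322 for BAL17VII against PBS, against BAL17 and between the days. The mean of its probe sets turned Hk1 to -0.037 in BAL17 day 21 against PBS. The B lineage covariate gave 348 genes between the implanted lines and turned Stap1 to 0.22, Cd2 to 1.182 and Ms4a1 to 0.104. Striatum and cortex covariates, added after the data were seen and partly circular by construction, gave 599 genes there (288 higher, 311 lower) and 0 between the days (2284 and 651 in limma before adjustment). They turned Neurod6 to -0.058, Vxn to -0.053, Tbr1 to -0.027, Satb1 to -0.145, Camk2a to -0.037, Cd34 to -0.071, Drd2 to 0.212 and Drd1 to 0.021. Split controls gave overlaps of 201.5, 1582.5, 188.5 and 9 calls in the order given above for the shared lists. Leaving out 1 array gave 3099 to 3398 genes in the lines, 4467 to 5638 in BAL17 day 21 and 2565 to 3453 in day 28 against PBS, and 1761 to 3790 between the implanted lines, lowest without BAL17VII replicate 1. For BAL17VII against PBS it gave 244 (without BAL17VII replicate 2) to 1285 (replicate 4), with 260 without replicate 3 and 357 without PBS replicate 4 or 5. Between the days it gave 45, 62 and 109 without day 28 replicates 1, 3 and 5, and 65, 294, 99 and 78 without day 21 replicates 1, 2, 4 and 5. List means gave 5 to 8 calls, with 5 from the median over the members. Low intensities approach the background of the array, which compresses fold changes of dim genes such as those of T cells.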

Other observations

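Pituitary transcripts reached very high levels in BAL17VII brains. Prl was 11.98, 13.20, 13.20 and 13.02 in replicates 1, 2, 3 and 5 and 5.57 in replicate 4, and the growth hormone gene Gh was 8.53, 12.33, 12.06 and 11.70 in the same brains and 5.49 in replicate 4. PBS brains had Prl between 5.79 and 10.46, and no BAL17 brain exceeded 5.63. These genes were read per brain after their values had been seen. In a single BAL17 brain of day 21, replicate 3, the antibody joining chain gene Jchain stood at 9.41, against 3.79 to 5.52 in its group. The choroid plexus gene Ttr stood at 9.66 in BAL17 replicate 4 of day 28, against 11.73 to 12.73 in its group.

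Hormone transcripts of the pituitary are not typical of lymphoma cells, so the share of pituitary and hypothalamic tissue in each sample may differ. Pmch was 11.02 in BAL17VII replicate 1 and also 9.66 in replicate 3, a brain with Top2a at 9.31. The reactive astrocyte difference of 0.127 could not settle where BAL17VII replicate 1 came from, and it does not bear on BAL17 brains. If the share of tissue differs, the falls of Prl in BAL17 brains against PBS would likely reflect tissue and not a response. That was not tested. Sections cut at a recorded level and stained for prolactin would decide this.

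Host macrophages might enter in step with the lymphoma. The macrophage mean followed the B lineage mean at r = 0.921, and it followed the MHC class II and interferon gamma genes above both sources at r = 0.797, a relation that fell to 0.628 (permutation p = 0.137) without the 2 farthest brains. Lymphoma cells that carry macrophage genes would give the same relation, and cultured BAL17 cells had Cybb at 7.65, with BAL17VII cells higher in 5 of 6 such genes tested. Without the genes above the filter in the cultured lines the relation with the B lineage mean was 0.806 and that with the class II and interferon gamma genes 0.685 (permutation p = 0.0365). Sorting of host and lymphoma cells from the same brain, with H2-Aa and Cd74 measured in each, would separate these readings.

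The class II difference between the lines may be one of culture conditions. Brain tissue dilutes any line difference, but dilution alone would leave BAL17VII brains higher and could not put H2-Aa in BAL17 brains at 8.73, above 5.73 in the line and 5.88 in PBS brains. H2-Aa differed by 4.43 in culture and by -0.71 in the brains, but genes outside class II also lost their difference, such as Trim30a (3.44 and 0.05) and Slc6a3 (-2.22 and 0.21). Of the class II and interferon gamma genes, 21.7% exceeded both sources in BAL17 brains at day 21 and 17.4% at day 28. BAL17 cells that raise class II genes once in the brain remain a hypothesis. It would be tested by exposing BAL17 cells to interferon gamma in culture and measuring Ciita and H2-Aa, with host cells removed in the brain samples.

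The striatal shift between days could come from the position of the section or from loss of striatal neurons. The PBS spread of 1.269 decides little, since it was 0.471 without PBS replicate 4. The mean of 4 midbrain dopamine markers was 6.87 at day 21 and 6.18 at day 28, with no overlap (6.64 to 7.14 and 6.02 to 6.36). Means at day 21 and day 28 were 8.59 and 9.16 for the cerebellum, 8.59 and 8.25 for the thalamus and 7.23 and 6.69 for the choroid plexus and ependyma, none of them tested here as a mean. Counting Drd1 and Penk cells in whole brains at both days would tell these apart.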
